A study of Homo sapiens with 3 samples.

How the data were processed

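Gene expression was measured by RNA sequencing in 3 established human cell lines, HEK-293T, HuH-7 and NCI-H1299, with 1 library per line. Per the labels' protocols, total RNA was extracted with Trizol and turned into libraries by a stranded method that removes ribosomal RNA. The authors deposited 1 table of FPKM values, that is, fragments or reads scaled to gene length and to the library total, for 41768 genes with a gene symbol and a class for each. HISAT, with no version, and the genome build hg38 are named in the submitters' processing notes. The read counter, the gene annotation, the strand setting and any filter are not given in the sources used here, so reads of a gene and of an antisense partner, or of a gene and its near-identical copies, cannot be told apart. Each column was matched to a cell line by the line's name in the column header. A letter that ends 2 of the 3 headers is not explained in the sources used here, and no column of another sample was present.

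The unit came from the values. Low values of one gene in different libraries stood in ratios of small whole numbers times 1 constant per pair of libraries, so whole reads had been divided by a gene length and by a library total. Solving for the totals, and taking the largest that fitted, gave 12647036 reads for HEK-293T, 26172404 for HuH-7 and 8677234 for NCI-H1299. With these totals, 27897 of the 27908 genes above 0 in any library (99.96%) had a whole gene length that made every value a whole number of reads, to within the last printed digit and a relative tolerance of 1e-10. With totals set 0.1% too high as a control, 2.50% of the genes did. The reads given per gene are the smallest that fit. They summed to 95.9%, 97.2% and 96.2% of the totals of HEK-293T, HuH-7 and NCI-H1299, so intervals made from them are, if anything, too wide. Reads of mitochondrial genes were instead computed from the gene spans in the RefSeq annotation. The reads served only for intervals, bounds and depth, and no count test was run, since each group holds 1 library.

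Comparisons were made on log2((FPKM + 1) / (FPKM + 1)). A log2 ratio on this scale understates the change of genes with low values. Because there was 1 library per line, a fixed rule of size replaced a test: a gene was called apart in a pair when the ratio was at least 4-fold, among genes at an FPKM of at least 1 in at least 1 of the 2 libraries. A gene was called enriched in a line at an FPKM of at least 5 there and, with 1 added to each value, at least 5-fold above each of the other 2 libraries. Folds printed for single genes are ratios of FPKM with nothing added, and their 95% intervals are exact conditional (Clopper-Pearson) intervals from the reads of both libraries. A fold against a library at 0 reads was computed against a floor of 3 reads per library and is given as a lower bound. This bound is not the lower end of the 95% interval, which can be smaller. For APOB in HuH-7 over HEK-293T that end was 36756, against a bound of 45196. At a gene length of 1000 bases that floor equals 0.237 FPKM in HEK-293T, 0.115 in HuH-7 and 0.346 in NCI-H1299. Intervals and floors cover counting error only. Several genes that most cells use, among them HK1, ALDOA, HSP90B1 and RPS29, were at or near 0 in every library, so a gene at 0 is described as listed at 0 and not as absent. These 4 genes were picked after their values were seen.

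Gene groups were 38 lists of cell type markers, pathways and gene families, of which 4 members were not in the table. The results of 1 list are not given here. For each list and pair, the members at an FPKM of at least 1 in either library were counted as measured, the members at least 2-fold higher or lower were counted, and the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart in the text when its median lay at or below the 2.5th or at or above the 97.5th percentile of those lists. This describes the libraries and is not a p-value. Chromosomes were compared by the median log2 ratio of genes at an FPKM of at least 5 in both libraries, less the median of all such genes, with bootstrap intervals from 2000 draws. Gene positions came from the RefSeq annotation of GRCh38, the same build as hg38, by symbol, older symbol or gene number, and were found for 90.7% of the genes. Transcript GC content came from the longest transcript of each symbol in GENCODE release 29, found for 70.4% of all genes. Y-linked genes and XIST were left out of the chromosome comparison, and 28 genes whose names had turned into calendar dates are not named.

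Named genes followed a rule: for each line, the 20 genes with the largest smaller-of-2 log2 ratio against the other libraries among genes at an FPKM of at least 10 there; for each pair, the 10 with the largest ratio in each direction, with the same minimum; in each list, up to 6 members with the largest absolute ratio, and any member of a list of at most 11 genes; the 10 genes of highest FPKM in each library; and checks of the labels that included ALB, AFP, NEFL, NEFM, PAX2, NKX2-1, GAPDH and ACTB. Clone names, small RNA names, ribosomal RNA, XIST and Y-linked genes were not named outside the lists. The groups, the rules, the gene lists, the named-gene rule and a first set of alternatives were chosen before the data were examined. That set covered pseudocounts of 0.1 and 5, other filters and sizes of change, mRNA genes only, rows summed by symbol, and 3 other scalings of the libraries: a common sum of all values, median-of-ratios factors and the upper quartile.

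Other steps were chosen after seeing the data: a scaling by the sum over genes other than mitochondrial and short noncoding RNA genes, counts without those genes, list medians less the median of all measured genes in the pair, the centring of log2 ratios in 20 bins of transcript GC content or of gene length, and random lists matched on GC content or length as well as expression, in 8 bins of each. In the centring by chromosome, the median of a bin was at first taken over all its genes. It was changed after the first result was seen to the median over genes of other chromosomes, because a chromosome that fills a bin would otherwise centre itself.

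The recovery of reads, the 4-fold rule, the intervals, the percentile rule, the call of genes enriched in HEK-293T and the centring of chromosome 19 by GC content were tested on simulated data. The bootstrap by chromosome, the centring by length, lists matched on GC content or length, the scalings and the call of genes enriched in HuH-7 or NCI-H1299 were not. Reads were drawn for the genes of the table from the measured values, at library totals drawn at random. The totals of the simulated table of 26653 genes were recovered with an error of 0 reads, 100% of its genes came out whole, 84.4% got their true reads in every library and 1 got more. At the 4-fold rule, 96%, 98% and 98% of genes changed by 6-fold were called in simulations of HuH-7 and HEK-293T (14661 genes), NCI-H1299 and HEK-293T (14686 genes) and HuH-7 and NCI-H1299 (14636 genes). For changes of 8-fold the shares were 100%, 100% and 96%, for 16-fold they were 100% in each pair, and for 2-fold they were 0%, 0% and 2%. The changed genes were drawn among genes at an FPKM of at least 10 in the measured library, so these shares do not describe genes at lower values. The 4-fold rule also called 10, 13 and 43 unchanged genes in these pairs. Intervals held a ratio of 1 for 95.8%, 94.9% and 96.0% of 1000 unchanged genes. These genes were picked above a minimum number of reads, so intervals of genes with few reads were not tested. Of unchanged lists, 4.5%, 2.5% and 8.5% stood apart by the percentile rule, and of lists raised by 1 on the log2 scale, 100% did in each pair. Both simulated libraries of a pair were drawn from the values of 1 measured library, so their ratios spread by counting error only. The measured ratios spread more: random lists matched to the 24 cholesterol synthesis genes ran from -1.64 to -0.25 (central 95%, HuH-7 over HEK-293T). The shares for lists thus do not describe the rule on the measured pairs. In simulated HEK-293T data of 41768 genes, genes at a mean FPKM of at least 10 over the libraries were raised by 8-fold. Of these, 100% were called enriched, with 0 unchanged genes called. Raised genes at lower values were not simulated. On a made-up GC trend over 5201 genes, centring moved the chromosome 19 median from -1.06 to 0.03 without a shift of its own, and from -2.05 to -0.97 with a shift of -1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.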

Results

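RNA levels were compared between 3 established human cell lines: HEK-293T, an embryonic kidney line that carries the SV40 large T antigen; HuH-7, a hepatocellular carcinoma line; and NCI-H1299, a lung carcinoma line. Each line was represented by 1 library, so no difference given here has a replicate check. Library totals were 12647036 reads for HEK-293T, 26172404 for HuH-7 and 8677234 for NCI-H1299. At an FPKM of at least 1, 14311 genes were detected in HEK-293T, 11260 in HuH-7 and 14375 in NCI-H1299. Of these, 9407 genes were detected in all 3 libraries. Genes detected in a single library numbered 2197 in HEK-293T, 730 in HuH-7 and 2462 in NCI-H1299. These counts depend on the scaling. Scaling by the sum over genes other than mitochondrial and short noncoding RNA genes had factors of 1.03 for HEK-293T, 2.20 for HuH-7 and 1.44 for NCI-H1299. For those other genes the FPKM minimum was thus strictest in HuH-7, and detected genes were not counted again with that scaling. Across the 17964 genes detected in any library, Pearson's r on log2(FPKM + 1) was 0.68 between HuH-7 and HEK-293T, 0.64 between NCI-H1299 and HEK-293T and 0.65 between HuH-7 and NCI-H1299. The Spearman values were 0.66, 0.61 and 0.63. The order of the pairs changed with the filter. Across the 5170 genes at an FPKM of at least 5 in all 3 libraries, Pearson's r was 0.64, 0.71 and 0.66 in the same order. These are correlations across genes, which are not independent replicates.

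The libraries differed in the kinds of RNA they held. Genes of the mitochondrial genome made up 65.1% of the FPKM sum in HuH-7, 2.29% in HEK-293T and 8.05% in NCI-H1299. The FPKM sum weights short genes more than reads do: with reads computed from the gene spans, mitochondrial genes held 38.1% of the library total in HuH-7, 0.873% in HEK-293T and 3.40% in NCI-H1299. Nuclear genes of short noncoding RNAs made up 19.8% of the FPKM sum in NCI-H1299, 3.54% in HEK-293T and 0.944% in HuH-7. Nuclear mRNA genes made up 82.4% in HEK-293T, 66.8% in NCI-H1299 and 30.6% in HuH-7. The genes of highest FPKM in HuH-7 were ND4L and ATP8, mitochondrial genes of respiratory complex I and of the ATP synthase, at 80599 and 66436. Among the highest in HEK-293T were RPS2P5, a pseudogene of a ribosomal protein gene, at 4131 and RPS4X, a ribosomal protein gene, at 3829. In NCI-H1299 the highest were the structured noncoding RNAs RN7SK, RN7SL1 and RN7SL2, at 41689.6, 12050 and 9815, and below them stood the mitochondrial genes ATP6 and COX1, at 5260.3 and 4651, and GAPDH, a glycolytic enzyme, at 4380.4. The level of GAPDH was 2623 in HEK-293T and 1302 in HuH-7, and that of ACTB, a cytoskeletal actin, was 1011 in HEK-293T, 1366 in HuH-7 and 2756 in NCI-H1299.

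**Figure D1:**
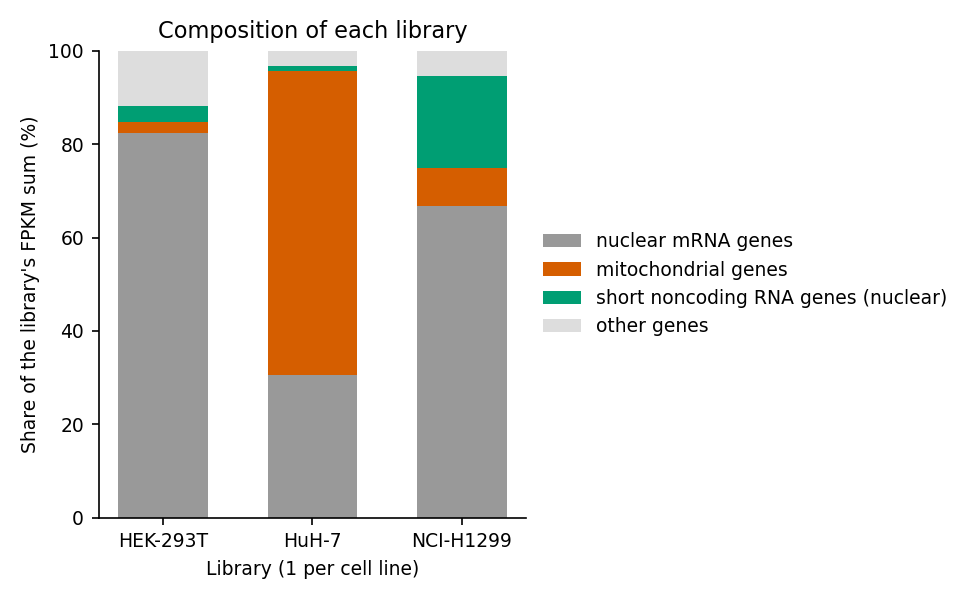
Share of each library's FPKM sum (y axis, %) taken by nuclear mRNA genes, mitochondrial genes, nuclear short noncoding RNA genes and other genes, in 1 library per cell line (x axis). Mitochondrial genes hold 65.1% of the sum in HuH-7 (38.1% of its reads), and short noncoding RNA genes hold 19.8% in NCI-H1299.

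Genes enriched in one line numbered 854 in HEK-293T, 333 in HuH-7 and 794 in NCI-H1299. In HuH-7, 293 of them were mRNA genes, and the strongest encoded plasma proteins of the liver: AFP, APOA2, ALB, APOB and FGB. The strongest in NCI-H1299 were RPPH1 and RMRP, the RNA parts of the nucleases RNase P and RNase MRP, then core histone genes such as HIST1H3F and HIST1H2AM, and MAGEA4, a germline antigen expressed in tumours. In HEK-293T, 435 of the enriched genes were mRNA genes and 298 belonged to the class that holds pseudogenes. The strongest mRNA genes there included IRS4, an adaptor of insulin signalling, at an FPKM of 170.2 against 0.0238 in HuH-7 and 0.0360 in NCI-H1299; TSC22D3, a glucocorticoid-induced regulator, at 298; and DDIT4, an inhibitor of mTOR signalling, at 231. The mitochondrial creatine kinase genes CKMT1A and CKMT1B stood at 77.7 and 87.3. Without mitochondrial and short noncoding RNA genes, the enriched genes numbered 798, 305 and 483 in HEK-293T, HuH-7 and NCI-H1299. The order of the lines turned with the scaling. In the same order, the counts were 551, 658 and 564 with the upper quartile, 600, 468 and 725 with median-of-ratios factors and 1329, 347 and 1461 with a common sum.

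Genes of secreted hepatocyte proteins were higher in HuH-7 than in HEK-293T, as were most liver transcription factors. All 42 measured genes of secreted hepatocyte proteins were at least 2-fold higher in HuH-7, with a list median 7.12 above the median of all genes on the log2 scale. AFP, the fetal counterpart of albumin, had an FPKM of 3579 in HuH-7 and 1 read in HEK-293T, a ratio of 92292 with a counting interval of 16564 to 3645365. ALB, albumin, stood at 1379.9 against 0.0352, also 1 read. The 2 genes are neighbours on chromosome 4 of GRCh38, ALB from position 73404287 to 73421482 and AFP from 73436221 to 73456174. APOB, the structural protein of low-density lipoprotein, at 759, was at least 45196-fold higher, and FGB, a fibrinogen chain, at 728, at least 11134-fold. Of 18 liver transcription factors, 12 were at least 2-fold higher and 3 lower (median 3.53 above all genes), among them NR1H4, the bile acid receptor FXR, at 28.5 against a listed 0, and FOXA2, a pioneer factor of liver development, at 30.02 against 0.392. Of 19 genes of xenobiotic and bile acid handling, 15 were higher and 1 lower (2.60 above all genes), including the glutathione transferase GSTA1 at 32.4 against a listed 0 and the cytochrome P450 gene CYP3A5 at 24.0 against 0.332.

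The whole distribution was shifted in this pair: the median log2 ratio of all measured genes was -1.04, and list medians are given here relative to it. Folds and FPKM of single genes and the 2-fold counts are as deposited and include the shift. Of 20 genes of epithelial junctions and keratins, 12 were at least 2-fold higher and 2 lower (2.48 above all genes). Among them were CLDN1, a tight junction protein, at 129 against 0.389, and KRT19, a keratin, at 62.1 against 0.161. SPINT2, a membrane protease inhibitor, went the other way, at a listed 0 against 7.94. Mesenchymal and matrix genes were split, 16 higher and 17 lower of 39, with a median 1.15 above all genes. The sign of the list's median before the shift was taken off turned with the scaling. With no filter on low values, the median of all genes was 0, so no shift was taken off, and the list median was -0.068. FN1, fibronectin, was 56.9-fold higher (53.9 to 60.1), while COL6A1, a collagen VI chain, was 112-fold lower and SNAI2, a repressor of epithelial genes, was at a listed 0 against 24.7. Of 14 oncofetal and let-7 axis genes, 8 were higher and 3 lower (2.53 above all genes). They included PEG10, a retrotransposon-derived imprinted gene, at 263 against 0.179, and IGF2, a fetal growth factor, at 279 against 0.811.

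HEK-293T held patterning genes that were low or at a listed 0 in HuH-7. All 9 measured HOXB genes and all 5 HOXD genes were at least 2-fold lower in HuH-7 (medians -2.56 and -2.98 relative to all genes), as were 7 of 11 HOXA genes (-2.25). These homeobox genes set position along the body axis. HOXB9 stood at 97.51 in HEK-293T and HOXD13 at 43.2, both against a listed 0, and HOXA5 at 58.4 against 1.36. Of 6 HOXC genes, 4 were at least 2-fold lower and the list median of -0.49 lay inside the range of matched random lists. Of 13 genes of kidney and urogenital development, 11 were lower and 1 higher (-1.16), among them CITED1, a marker of the nephron progenitor, at 80.0 against 0.0307, and SIX2, which maintains that progenitor, at 15.2 against 0.122. Of 19 neuronal genes, 12 were lower and 0 higher (-0.75); the neurofilament genes NEFM and NEFL stood at 16.2 and 5.35 against a listed 0. Of 7 cancer-testis antigens, 6 were lower and 1 higher (-1.21, and 0 with no filter on low values), with MAGEA3 at 0.0638 against 4.75 and MAGEB2 at 14.5 against 2.21. PAX2, a kidney regulator, was at 1.30 in HEK-293T, 0.00923 in HuH-7 and a listed 0 in NCI-H1299.

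**Figure D2:**
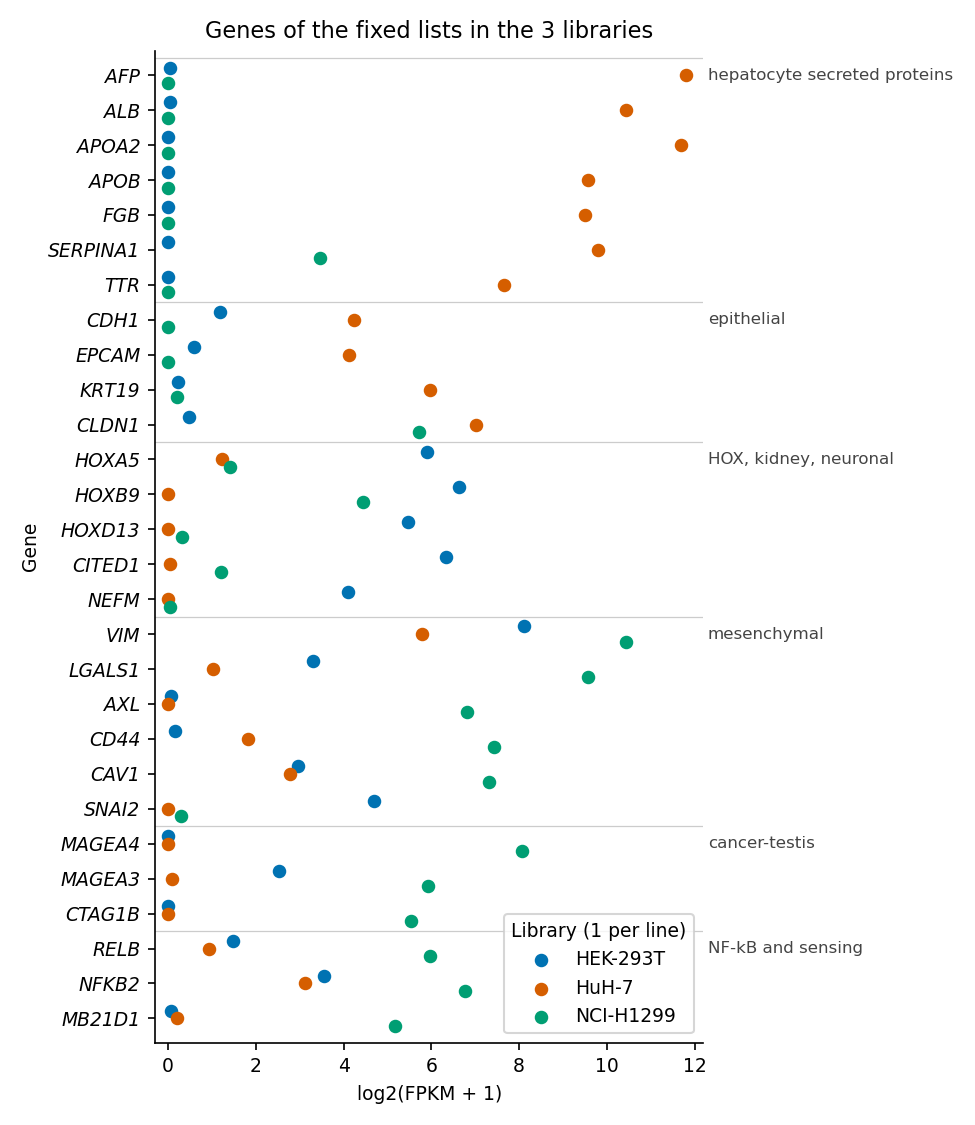
Level of list genes (y axis), chosen after their values were seen, as log2(FPKM + 1) (x axis) in 1 library per cell line (colours, offset vertically). AFP reaches an FPKM of 3579 in HuH-7, HOXB9 97.51 in HEK-293T and MAGEA4 265 in NCI-H1299, each against 0 or low values in at least 1 other line.

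Inflammatory and stress genes also separated HuH-7 from HEK-293T. Of 19 genes of inflammatory signalling, 12 were at least 2-fold higher in HuH-7 and 0 lower (2.44 above all genes). The chemokine gene CCL20 stood at 308, at least 1093-fold higher than in HEK-293T, CXCL5, another chemokine, at 55.2 against a listed 0, and ICAM1, a leukocyte adhesion receptor, at 56.9 against 0.0731. Of 27 NRF2 target genes, 14 were higher and 8 lower (2.19 above all genes). The aldo-keto reductase AKR1C1 was 323-fold higher (126 to 1186) and NQO1, a quinone reductase, 41.6-fold (33.4 to 52.5), while AKR1B1 was 10.7-fold lower. Of 35 virus receptors and entry factors, 12 were higher and 5 lower (1.45). HAVCR1, the hepatitis A virus receptor, was at 94.2 against a listed 0, and CD81, a tetraspanin that hepatitis C virus binds, was 19.5-fold lower in HuH-7. Of the 5 measured blood and endothelial cell markers, 4 were higher and 1 lower (2.78, and 0 with no filter on low values): LYZ, lysozyme, at 223 against a listed 0, and CD68, a lysosomal protein, at 4.71 against 1.02, for example.

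Lists whose medians lay inside the range of matched random lists still held genes with large ratios in this pair. Among 31 interferon pathway genes, 8 were at least 2-fold higher and 11 lower, with a median of 0.58 relative to all genes. MX2, an interferon-induced GTPase, stood at 35.2 in HuH-7 against a listed 0, and IFITM1, a membrane protein that restricts virus entry, at 0.160 against 15.5. Of 12 genes of innate nucleic acid sensing, 2 were higher and 2 lower (0.94), with MYD88, an adaptor of Toll-like receptors, at 20.3 against 0.165 and TMEM173, which encodes STING, at 0.123 against 2.84. Antigen presentation had 3 higher and 10 lower of 14 (-0.40); HLA-B was at 0.0243 against 11.2 and HLA-C at 1.31 against 70.8. The urea cycle and amino acid list had 4 higher and 4 lower of 14 (0.40), with ARG1, the arginase of the liver, at 9.09 against a listed 0 and ASS1, argininosuccinate synthase, at 5.29 against 102. Glycolysis and hypoxia genes had 3 higher and 13 lower of 26 (0.13), and LDHB, a lactate dehydrogenase subunit, was 3387-fold lower in HuH-7, at 0.273 and 11 reads. Lung lineage genes had 1 higher and 4 lower of 6 (-0.74), adrenal and neural crest genes 0 higher and 4 lower of 5 (-0.48), and RNA modification enzymes 1 higher and 10 lower of 23 (0.14). ETV5, TFAP2A and PUS1 had the largest ratios in those lists, at 15.3 against 0.135, 0.0301 against 18.8 and 4.23 against 38.4.

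Ribosomal protein, nuclear respiratory chain and cell cycle genes were lower in HuH-7 than in HEK-293T beyond the shift of all genes. Of 74 cytosolic ribosomal protein genes, 62 were at least 2-fold lower and 2 higher (-0.99), including RPL13 at 7.95 against 334. Across genes, the log2 ratio of HEK-293T over HuH-7 fell with gene length (Spearman -0.35). Random lists also matched on length had a median of 1.09 in that direction, against 2.03 for the ribosomal protein genes. Both values include the shift of all genes, which was -1.04 for HuH-7 over HEK-293T. The 1.09 of the random lists thus lay close to the size of the shift itself. Of 37 nuclear genes of the respiratory chain, 26 were lower and 0 higher (-0.74), including the complex I gene NDUFS7 at 2.33 against 41.5, while 14 of 15 mitochondrially encoded genes were higher (6.33), including ND4, also of complex I, at 56499 against 589. Cell cycle and proliferation genes were lower in 27 and higher in 3 of 44 (-0.58): CDT1, a replication licensing factor, was 24.8-fold lower, MYC 10.7-fold lower, and MYCN, a MYC relative, 35.2-fold higher. Tumour suppressors and cell cycle inhibitors were lower in 14 and higher in 0 of 21 (-0.93), with BAP1, a deubiquitinase, 27.1-fold lower and the cell cycle inhibitor CDKN1A 27.4-fold lower. In 6 lists besides the mesenchymal genes, the median lay above that of all genes while its sign before the shift was taken off turned with the scaling: cholesterol synthesis (0.99, 5 higher and 9 lower of 24), the unfolded protein response (0.96, 2 and 10 of 23), proteasome subunits (0.72, 2 and 8 of 31), histones (1.10, 2 and 1 of 10), microRNA biogenesis (1.04, 2 and 2 of 16) and long noncoding RNAs (1.27, 7 and 4 of 16). With no filter on low values, the median of all genes was 0, with 23804 genes below an FPKM of 1 in every library. The shift was then no longer taken off, and the medians of all but the long noncoding RNAs lay below 0. Cholesterol synthesis, the unfolded protein response and the proteasome had medians of -0.049, -0.079 and -0.32 before the shift was taken off. These were the same with and without the filter. Among members of the 6 lists, the sterol synthesis enzyme HMGCS1 was at 68.8 against 17.7, ASNS, asparagine synthetase, at 16.96 against 282, and the liver cancer RNA HULC at 81.6 against 0.163. Structured noncoding RNAs were lower in 4 and higher in 0 of 8 (0.11, inside the range of matched lists), with RN7SL2, an RNA of the signal recognition particle, at 1.41 against 559.

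By the 4-fold rule, 701 genes were higher in HuH-7 and 3503 lower among 15502 compared, so 16.7% of the called genes were higher. That share was 11.3% with each library rescaled to a common sum, 33.6% with median-of-ratios factors, 47.4% with the upper quartile and 43.4% with the sum over genes other than mitochondrial and short noncoding RNA genes. With median-of-ratios factors the 2-fold counts also turned to more genes higher than lower in 8 lists where this was not so as deposited: 11 higher and 7 lower for the interferon pathway, 4 and 1 for nucleic acid sensing, 5 and 3 for the urea cycle and amino acid list, 18 and 15 for mesenchymal genes, 9 and 3 for cholesterol synthesis, 7 and 4 for the unfolded protein response, 9 and 3 for the proteasome and 4 and 2 for microRNA biogenesis. The log2 ratio fell with transcript GC content across genes (Spearman -0.45), and with random lists matched on GC content as well, 5 lists came inside the range: tumour suppressors (percentile 8.77), proteasome subunits (92.3), microRNA biogenesis (93.4), long noncoding RNAs (97.2) and neuronal genes (2.54), while the interferon list came out of it (97.9).

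The largest list medians of NCI-H1299 over HEK-293T were those of histones, structured noncoding RNAs, inflammatory genes and cancer-testis antigens. Of 26 replication-dependent histone genes, which encode the histones of S phase, 25 were at least 2-fold higher in NCI-H1299 and 0 lower, with a list median 6.48 above that of all genes, whose own median was -0.08. HIST1H2BC stood at 650 against 0.181, which is 1 read. Of 15 structured noncoding RNAs, 14 were higher and 1 lower (4.54). RN7SK, which holds back transcription elongation, stood at 41689.6 against 4.53, and RPPH1 at 4022 against 1.16. Of 17 cancer-testis antigens, 15 were higher and 1 lower (3.48); MAGEA4 stood at 265, at least 986-fold higher, and CTAG1B, the antigen NY-ESO-1, at 45.1, at least 142-fold higher. These differences in histone and structured RNA genes stood beside the 19.8% share of short noncoding RNA genes in the NCI-H1299 library. Loss of RNA without a poly(A) tail from the HEK-293T library may account for them, as weighed below.

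Signalling genes of inflammation and of nucleic acid sensing were higher in NCI-H1299. In the inflammatory list, 14 of 15 genes were at least 2-fold higher and 0 lower (3.49 above all genes). RELB, an NF-kB subunit, stood at 61.2 against 1.80, NFKBIA, the inhibitor of NF-kB, at 206 against 14.7, and LIF, a cytokine, at 29.2 against 0.458. In the list of innate nucleic acid sensing, 10 of 14 were higher and 0 lower (1.71). MB21D1, which encodes the DNA sensor cGAS, stood at 34.9 against 0.0439, and IFIH1, the RNA sensor MDA5, was 22.5-fold higher (14.3 to 37.4). Interferon pathway genes had 6 higher and 3 lower of 28 (0.17) and antigen presentation genes 7 and 5 of 16 (0.60), both inside the range of matched lists. IFITM3, an antiviral membrane protein, stood at 199 against 3.79, and TAPBP, tapasin of the peptide loading complex, at 21.7 against 1.31.

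In NCI-H1299, 18 of 40 mesenchymal and matrix genes were at least 2-fold higher and 11 lower (0.68 above all genes). The receptor kinase AXL stood at 111 against 0.05002, the hyaluronan receptor CD44 at 172 against 0.124, and the matrix protein THBS1 at 118 against 0.0683. In the epithelial list, 5 of 14 were higher and 4 lower (-0.24, inside the range). CLDN1 stood at 51.8 against 0.389, and the junction protein JUP at 0.953 against 43.3. Oncofetal genes were higher in 6 and lower in 2 of 12 (1.12), with PEG10 at 125 against 0.179 and HMGA2, a chromatin protein that let-7 represses, at 29.7 against 9.95. Virus entry factors had 11 higher and 10 lower of 34 (0.27, inside the range); the ephrin receptor EPHA2 was 28.9-fold higher (23.1 to 36.4). Of 16 genes of microRNA biogenesis and RNA silencing, 8 were higher and 0 lower (1.09), among them AGO2, which holds the guide RNA, at 56.8 against 8.16, and DICER1, which cuts precursors, at 49.1 against 7.08. Of 14 long noncoding RNAs, 5 were higher and 4 lower (0.64, inside the range), and MALAT1, a nuclear RNA, stood at 1318 against 1.44.

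The HOXD, HOXA and kidney development lists had lower medians in NCI-H1299 than in HEK-293T. All 5 HOXD genes were at least 2-fold lower (-3.79), with HOXD13 at 0.248 against 43.2. The HOXA genes had 7 of 11 lower (-1.74) and the HOXC genes 4 of 7 lower and 1 higher (-1.35), with HOXA10 at 1.57 against 46.8 and HOXC8 higher, at 25.8 against 2.90. The HOXB list, with 4 of 9 lower and 2 higher (-0.64), lay inside the range; HOXB4 stood at 36.0 against 2.53. Kidney genes were lower in 10 and higher in 2 of 13 (-1.82), with CITED1 at 1.30 against 80.0. Liver transcription factors were lower in 5 and higher in 1 of 9 (-1.25), with CEBPA at 0.657 against 11.7. The unfolded protein response was lower in 12 and higher in 0 of 23 (-1.38), including CHAC1, a glutathione-degrading enzyme, at 3.40 against 50.3, and ASNS at 55.3 against 282. Cholesterol synthesis was lower in 10 and higher in 1 of 23 (-0.82), with MSMO1, a sterol oxidase, at 7.51 against 27.2. Ribosomal protein genes were lower in 52 and higher in 5 of 74 (-1.51) and nuclear respiratory chain genes lower in 19 and higher in 0 of 37 (-1.09), with RPL36 at 90.6 against 2046 and NDUFA1 at 17.3 against 230.5. Across genes, the log2 ratio of HEK-293T over NCI-H1299 fell with gene length (Spearman -0.39). Only the ribosomal protein genes were set against random lists also matched on length. Those random lists had a median of 0.77 for HEK-293T over NCI-H1299, against 1.60 for the ribosomal protein genes. Neither value has the median of all genes taken off, which was -0.08 for NCI-H1299 over HEK-293T. Mitochondrially encoded genes were higher in 12 and lower in 2 of 15 (2.43). The lower ones were the mitochondrial ribosomal RNAs RNR1, at 32.5 against 326, and RNR2, at 23.1 against 847.

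The remaining lists of this pair lay inside the range of matched random lists, apart from the blood and endothelial markers. In that list of 3, 2 were higher and 1 lower (2.18), with CD68 at 31.0 against 1.02, and the sign of its median turned with the scaling to a common sum (-1.31) and was lost with no filter on low values (0). Cell cycle genes had 7 higher and 6 lower of 43 (0.11), with CDK6 at 129 against 6.45 and CCND1 at 194 against 12.002, a kinase and a cyclin of the G1 phase. Tumour suppressors had 4 higher and 9 lower of 22 (-0.68), with the chromatin remodeller SMARCA4 at 11.3 against 93.7. Neuronal genes had 7 higher and 8 lower of 21 (0.18), with INA, a neurofilament protein, at 67.1 against 5.60 and NEFM at 0.0352 against 16.2. Counts of higher and lower genes were 2 and 3 of 8 for the lung lineage (0.51), 0 and 1 of 5 for adrenal and neural crest genes (-0.49), 1 and 2 of 4 for hepatocyte proteins (-0.87), 1 and 3 of 6 for xenobiotic handling (-0.97) and 0 and 5 of 10 for amino acid catabolism (-1.10). They were 4 and 8 of 21 for NRF2 targets (-0.18), 2 and 11 of 26 for glycolysis (-0.29), 4 and 8 of 31 for the proteasome (-0.21) and 3 and 4 of 23 for RNA modification (0.00146). NKX2-1, the lung and thyroid regulator, stood at 0.0986 against 2.33 in HEK-293T and 0.0490 in HuH-7. OSGIN1, an NRF2 target, stood at 64.1 against 0.204 and ASS1 at 0.624 against 102.

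By the 4-fold rule, 1666 genes were higher in NCI-H1299 and 1793 lower among 17234 compared, so 48.2% of the called genes were higher. That share was 51.2% with each library rescaled to a common sum, 53.5% with median-of-ratios factors, 47.8% with the upper quartile and 62.6% with the sum over genes other than mitochondrial and short noncoding RNA genes, and without those genes 1071 genes were higher and 1690 lower. Among mRNA genes there were 717 and 1038. Large mRNA ratios toward HEK-293T included those of PRDX2 and GPX1, peroxide-reducing enzymes, at 387 against 0.111 and 275 against 0.585, and of TSC22D3, at 298 against 0.102. With median-of-ratios factors the balance of the 2-fold counts changed in 3 lists, to 7 higher and 4 lower for the proteasome, 4 and 2 for RNA modification and 8 and 8 for neuronal genes. With random lists matched on GC content as well, liver transcription factors (percentile 4.40) and the HOXC genes (2.85) came inside the range.

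Between HuH-7 and NCI-H1299, both carcinoma lines, liver and epithelial genes were higher in HuH-7, and mesenchymal and germline antigen genes higher in NCI-H1299. Histone genes were also higher in the NCI-H1299 library. Loss of RNA without a poly(A) tail from the HuH-7 library may account for that, as weighed below. In this pair the median of all genes was -1.01 and list medians are again relative to it. Of 42 hepatocyte proteins, 41 were at least 2-fold higher in HuH-7 and 0 lower (7.32); AFP was at least 21107-fold higher. Liver transcription factors were higher in 14 and lower in 1 of 17 (3.73), xenobiotic handling in 15 and 0 of 18 (3.52), and amino acid catabolism in 6 and 1 of 11 (2.40), with PROX1, a hepatoblast regulator, at 20.1 against 0.0406 and ARG1 at 9.09 against a listed 0. Epithelial genes were higher in 13 and lower in 1 of 20 (2.58): CDH1, E-cadherin, stood at 17.9 and EPCAM, an epithelial adhesion molecule, at 16.3, both against a listed 0. Mesenchymal genes were lower in 21 and higher in 10 of 37 (-1.05): LGALS1, galectin-1, was 733-fold lower and AXL at least 4583-fold lower in HuH-7, while FN1 was 66.7-fold higher (62.1 to 71.6).

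Other lists higher in HuH-7 than in NCI-H1299 were oncofetal genes (2.14, 8 higher and 3 lower of 14), NRF2 targets (1.63, 11 and 4 of 27), cholesterol synthesis (1.54, 8 and 4 of 24), blood and endothelial markers (2.72, 3 and 2 of 5, and 0 with no filter on low values) and mitochondrially encoded genes (4.32, 14 and 1 of 15). GPC3, a glypican of fetal liver, stood at 124 against a listed 0, FTH1, a ferritin chain, at 1586 against 75.9, and MSMO1 at 76.4 against 7.51. LYZ stood at 223 against a listed 0 and RNR2 at 23336 against 23.1. The unfolded protein response (1.29, 5 and 2 of 23) and virus entry factors (1.08, 12 and 10 of 36) were also above all genes, and the sign of both medians before the shift was taken off turned with the scaling. XBP1, a transcription factor of that response, was 5.57-fold higher (5.08 to 6.12), and DPP4, the receptor of MERS coronavirus, stood at 50.1 against 0.0886.

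Lists lower in HuH-7 than in NCI-H1299 were histones (-5.72, 25 lower and 0 higher of 26), structured noncoding RNAs (-4.47, 14 and 1 of 15), HOXB genes (-3.42, 7 and 0 of 7) and cancer-testis antigens (-3.25, 15 and 1 of 16). Antigen presentation (-0.71, 10 and 1 of 14) and cell cycle genes (-0.54, 28 and 1 of 42) were lower too. HIST1H2AG stood at 0.230 against 554, RMRP at 0.428 against 3920.5, HOXB4 at a listed 0 against 36.0 and MAGEA3 at 0.0638 against 59.4. TAP1, a peptide transporter, was 31.6-fold lower, HLA-B stood at 0.0243 against 12.19, and the replication factor CDT1 was 14.9-fold lower. These histone and structured RNA differences again stood beside the short noncoding RNA shares of 0.944% and 19.8%.

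The other lists of this pair lay inside the range of matched random lists. Counts of genes at least 2-fold higher and lower in HuH-7 were 6 and 13 of 21 for inflammatory signalling (-0.38), 1 and 9 of 15 for nucleic acid sensing (-0.66), 4 and 11 of 28 for the interferon pathway (0.47), 1 and 9 of 16 for microRNA biogenesis (-0.13) and 4 and 6 of 15 for long noncoding RNAs (0.96). They were 0 and 11 of 20 for tumour suppressors (-0.04), 4 and 13 of 25 for glycolysis (-0.01), 8 and 26 of 74 for ribosomal proteins (0.65), 3 and 7 of 31 for the proteasome (0.65), 1 and 12 of 37 for the nuclear respiratory chain (0.48) and 2 and 14 of 23 for RNA modification (-0.09). For lineages they were 2 and 5 of 7 kidney genes (-0.15), 1 and 11 of 14 neuronal genes (-0.63), 0 and 2 of 3 adrenal and neural crest genes (-0.73) and 0 and 3 of 5 lung genes (-0.03). In the homeobox clusters they were 0 and 1 of 7 for HOXA (0.65) and 2 and 2 of 6 for HOXC (0.45), and 1 HOXD gene was measured, too few for a median. CCL20 stood at 308 against 0.137 and CXCL5 at 55.2 against a listed 0, while RELB, at 0.922 against 61.2, and NFKB2, another NF-kB subunit, at 7.74 against 108, were higher in NCI-H1299. MB21D1 was 235-fold and CDKN1A 74.6-fold lower in HuH-7, and INA stood at a listed 0 against 67.1.

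By the 4-fold rule, 817 genes were higher in HuH-7 and 3222 lower among 15767 compared, so 20.2% of the called genes were higher. That share was 12.8% with each library rescaled to a common sum, 33.6% with median-of-ratios factors, 53.1% with the upper quartile and 33.7% with the sum over genes other than mitochondrial and short noncoding RNA genes. With median-of-ratios factors the balance of the 2-fold counts changed in 4 lists, to 7 higher and 1 lower for the proteasome, 2 and 1 for HOXA, 7 and 7 for the nuclear respiratory chain and 5 and 5 for long noncoding RNAs. The log2 ratio fell with transcript GC content (Spearman -0.36 across genes); with random lists matched on it as well, antigen presentation came inside the range (percentile 4.12) and microRNA biogenesis came out of it (2.30).

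**Figure D3:**
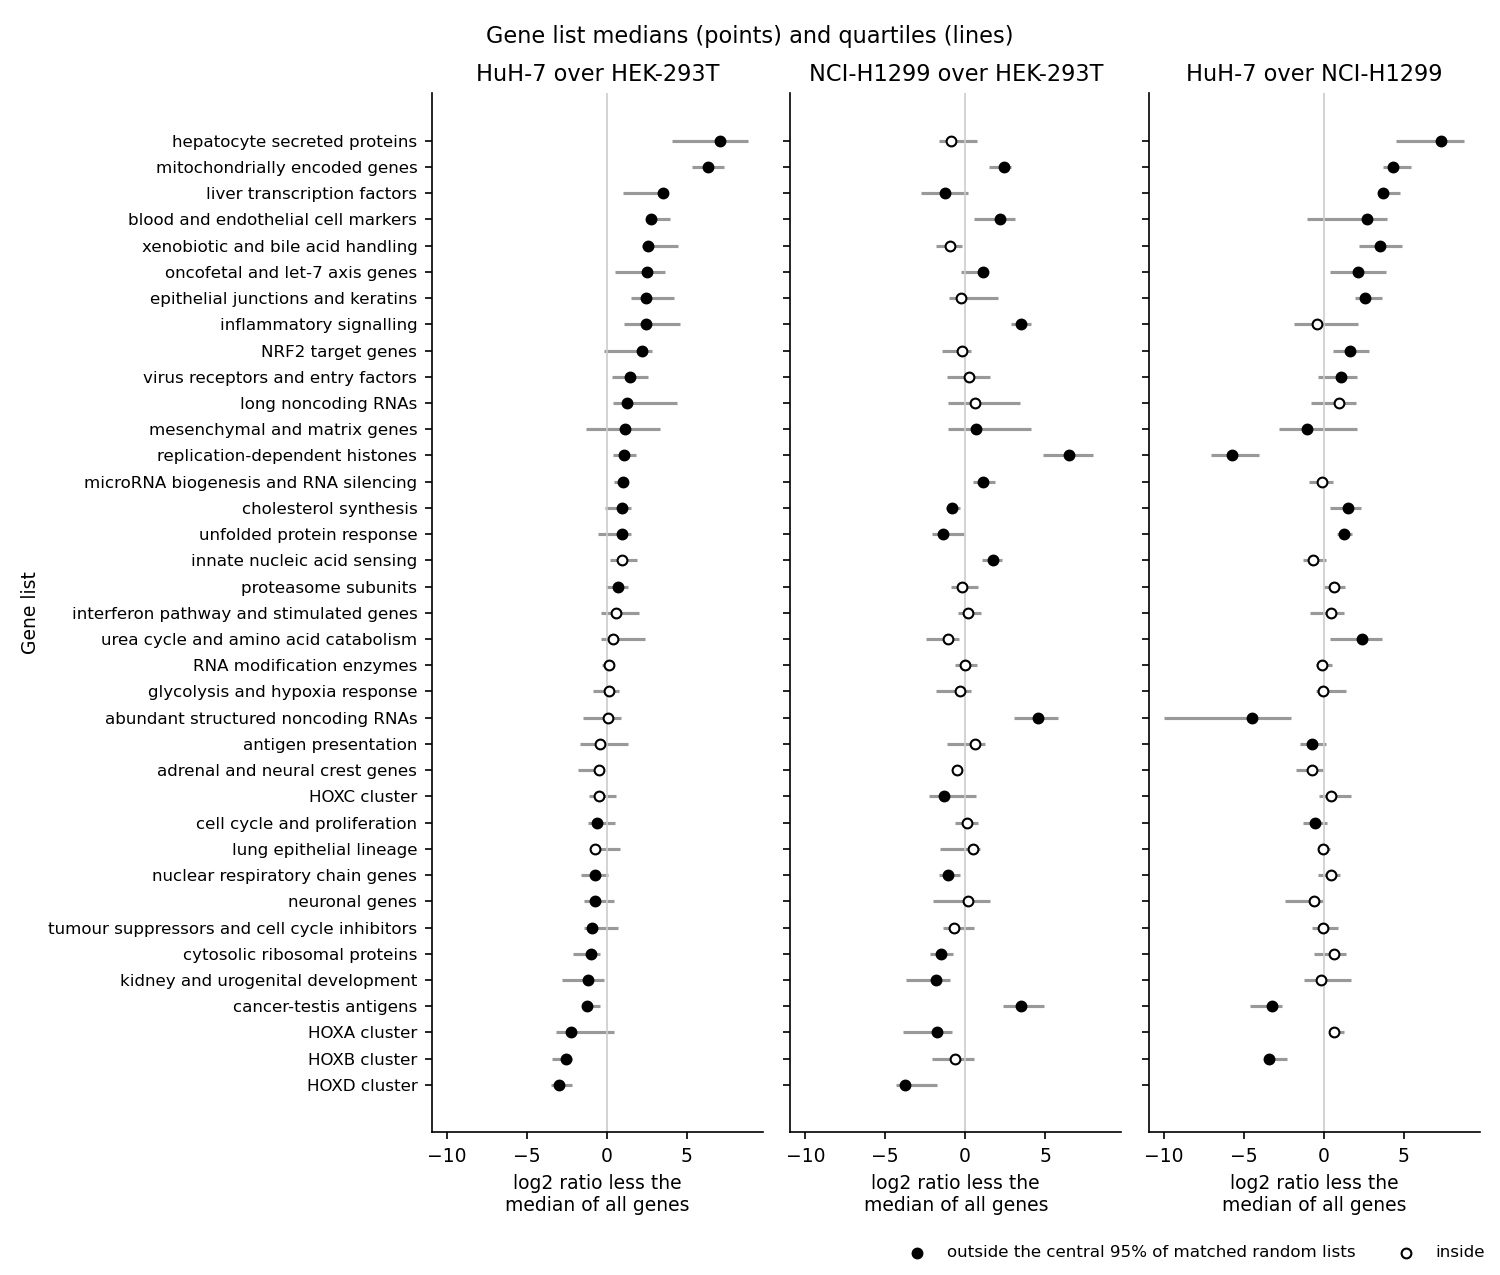
Median log2 ratio of each gene list less the median of all measured genes (x axis), with the quartiles as lines, for 37 of the 38 lists (y axis) in each pair of libraries. Filled points lie outside the central 95% of matched random lists; hepatocyte secreted proteins reach 7.12 and 7.32 in HuH-7, histones reach 6.48 in NCI-H1299 over HEK-293T, and for the lists named so in the text the sign turned with the scaling or the filter.

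Gene expression also varied by chromosome. In HuH-7 over HEK-293T, the 298 genes of chromosome 19 had a median log2 ratio of -1.22 relative to all genes compared (bootstrap interval -1.345 to -1.001), followed by chromosomes 22 (-0.85), X (-0.62), 16 (-0.58) and 17 (-0.43). Chromosomes 13 (0.67), 18 (0.63) and 8 (0.38) had the highest medians. In NCI-H1299 over HEK-293T the lowest were 22 (-0.68) and X (-0.54), and the highest 8 (0.58) and 18 (0.42). In HuH-7 over NCI-H1299, chromosome 19 stood at -0.86, 17 at -0.37 and 13 at 0.85. Median transcript GC content was 58.7% for chromosome 19, 52.9% for 22 and 41.6% for 13, and after centring in bins of GC content the chromosome 19 median of HuH-7 over HEK-293T was -0.36 (-0.45 to -0.20). The order of the chromosomes changed: 22 then stood at -0.24, 16 at -0.30, 17 at -0.18, 13 at 0.27 and 8 at 0.15, while X had the lowest median, at -0.59, and 18 the highest, at 0.52. In HuH-7 over NCI-H1299, chromosomes 6 (-0.39) and 8 (-0.31) were then lowest and 13 highest (0.63), with 19 at -0.22 and 17 at -0.18, and in NCI-H1299 over HEK-293T, 22 (-0.64) and X (-0.57) stayed lowest and 8 (0.55) and 18 (0.36) highest. The standard deviation over chromosomes in HuH-7 over HEK-293T went from 0.47 to 0.27.

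**Figure D4:**
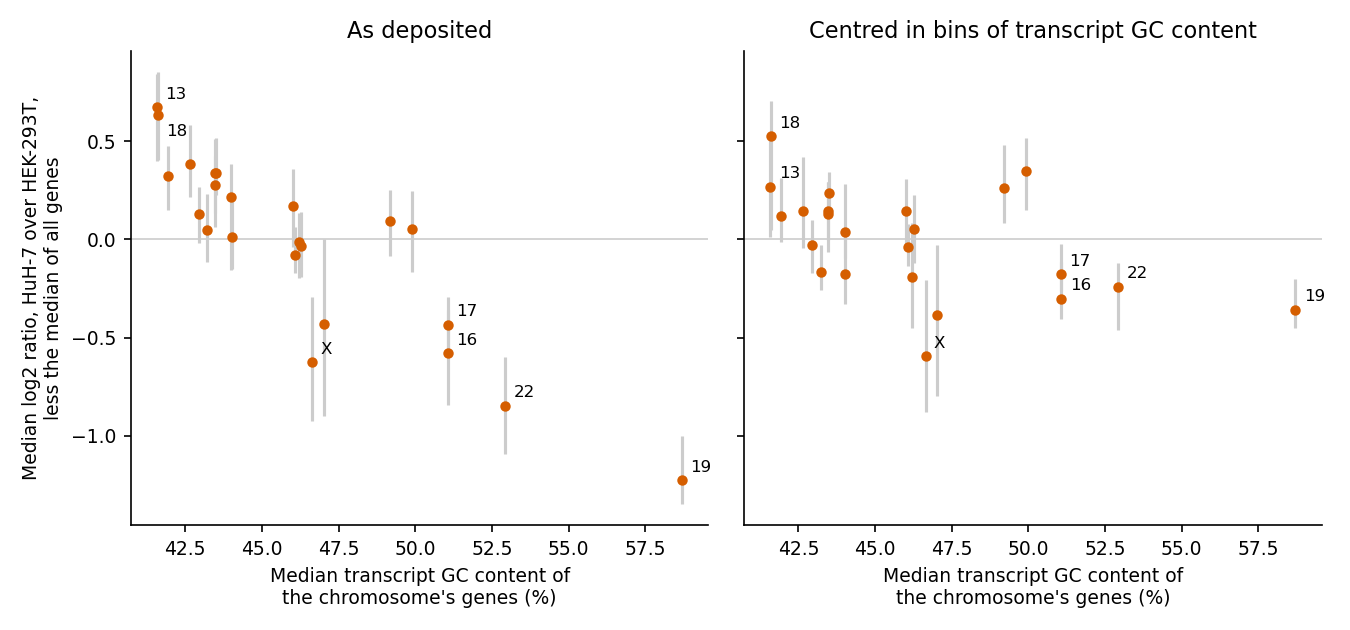
Median log2 ratio of each chromosome's genes, HuH-7 over HEK-293T, less the median of all genes (y axis), against the median transcript GC content of those genes in % (x axis), as deposited (left) and after centring in bins of transcript GC content (right). Points are chromosomes and lines are 95% bootstrap intervals; chromosome 19 moves from -1.22 to -0.36.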

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

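The settings "sum over genes other than mitochondrial and short noncoding RNA genes", "without mitochondrial and short noncoding RNA genes", the centring by GC content or length and random lists also matched on GC content or length were chosen after seeing the data, and so were list medians less the median of all genes; the other settings had been planned. No paired analysis was possible because each line had 1 library, and no library was left out. In each set of 3 values, the order is HuH-7 over HEK-293T, NCI-H1299 over HEK-293T and HuH-7 over NCI-H1299 for pairs, and HEK-293T, HuH-7 and NCI-H1299 for enriched or detected genes. Over all alternatives, 66 counts of detected, called or enriched genes stayed within 1.5 times the reported count and 57 did not. Of the values for lists, chromosomes, correlations and named genes, 21 reversed in sign, 274 moved beyond their spread without reversing and 1570 did neither. Counts of genes at least 4-fold apart moved with the size asked for, by construction. At 2-fold, 1727, 4318 and 1945 genes were higher and 7984, 4885 and 7918 lower; at 8-fold, 318, 692 and 384 were higher and 1321, 693 and 1022 lower. With a pseudocount of 0.1, 1270, 3179 and 1468 were higher and 5927, 3335 and 5779 lower; with 5, 264, 500 and 289 were higher and 1293, 627 and 864 lower, and 301, 145 and 249 were enriched. A 10-fold rule left 332, 180 and 357 enriched genes, and a minimum FPKM of 5 left 9345, 6468 and 9481 detected genes.

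Scaling moved the balance between lines. Scaled by the genes other than mitochondrial and short noncoding RNA genes, the median log2 ratio of HuH-7 over HEK-293T went from -1.04 to -0.13. For HuH-7 over NCI-H1299 it went from -1.01 to -0.57, and for NCI-H1299 over HEK-293T from -0.08 to 0.38. Leaving those genes out of the sum thus removed most of the shift of HuH-7 against HEK-293T and part of that against NCI-H1299. Other causes were not tested. With each library rescaled to a common sum, 5647 genes were lower in HuH-7 than in HEK-293T and 5760 lower than in NCI-H1299, 2541 were higher in NCI-H1299 than in HEK-293T, and 1329 were enriched in HEK-293T and 1461 in NCI-H1299. With median-of-ratios factors, 1112 genes were higher and 2201 lower in HuH-7 than in HEK-293T. With the upper quartile these were 1544 and 1715, the counts for HuH-7 and NCI-H1299 were 1715 and 1512, and 551 genes were enriched in HEK-293T and 658 in HuH-7. With the sum over genes other than mitochondrial and short noncoding RNA genes, 1629 were higher and 2122 lower in HuH-7 than in HEK-293T, 1441 were higher in HuH-7 than in NCI-H1299, and 656 were enriched in HuH-7. Among mRNA genes alone, and so among fewer genes, 717 were higher and 1038 lower in NCI-H1299 than in HEK-293T, 2142 were lower in HuH-7 than in NCI-H1299, and 435 were enriched in HEK-293T and 324 in NCI-H1299. Without mitochondrial and short noncoding RNA genes, 1071 were higher in NCI-H1299 than in HEK-293T and 483 enriched in it.

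Some list medians, before the median of all genes was taken off, reversed in sign; the cause was not tested. For HuH-7 over HEK-293T, cholesterol synthesis, proteasome subunits and the unfolded protein response went to 0.67, 0.40 and 0.61 with median-of-ratios factors, to 1.09, 0.83 and 1.02 with the upper quartile, and to 1.03, 0.76 and 0.97 with the sum over other genes. With a common sum, mesenchymal genes went to -0.47, microRNA biogenesis to -0.41, histones to -0.55 and long noncoding RNAs to -0.33. With no filter on low values, mesenchymal genes went to -0.068, microRNA biogenesis to -0.0047 and histones to -0.13. With a common sum, the unfolded protein response and virus entry factors went to -0.26 and -0.44 for HuH-7 over NCI-H1299, and the blood markers to -1.34 for NCI-H1299 over HEK-293T. Less the median of all genes in the same setting, lists that stood apart reversed as well. With a common sum, the blood markers of NCI-H1299 over HEK-293T went from 2.18 to -1.31. With no filter, where the median of all genes is 0, cholesterol synthesis, mesenchymal genes, the unfolded protein response, proteasome subunits, histones and microRNA biogenesis of HuH-7 over HEK-293T went to -0.049, -0.068, -0.079, -0.32, -0.13 and -0.0047. Because no shift was taken off in that setting, these values do not test the lists relative to all genes. With no filter, cancer-testis antigens of HuH-7 over HEK-293T went from -1.21 to 0, and blood markers went from 2.78, 2.18 and 2.72 to 0 in the 3 pairs. After centring by GC content, chromosomes 16 and 22 of HuH-7 over NCI-H1299 went to 0.024 and 0.12.

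Depth limits low values: 3 reads of a gene of 1000 bases equal an FPKM of 0.237 in HEK-293T, 0.115 in HuH-7 and 0.346 in NCI-H1299, so a gene at 0 in NCI-H1299 has the highest bound. With 1 library per line, the spread between cultures is unknown, and neither it nor a batch can be told from a difference between lines.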

Other observations

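Some genes with the largest ratios belonged to none of the lists. FHL1, a LIM domain protein of muscle, had an FPKM of 138 in HEK-293T, 18.5 in NCI-H1299 and 0.0132 in HuH-7. TSPO, a cholesterol-binding protein of the outer mitochondrial membrane, stood at 135.5 in HEK-293T, 31.0 in NCI-H1299 and 0.178 in HuH-7. LY6E, a membrane protein induced by interferon, stood at 104 and 67.8 in HEK-293T and NCI-H1299 and was listed at 0 in HuH-7. MIF, a cytokine, was among the 10 genes of highest FPKM in HEK-293T, at 2806 against 56.1 in HuH-7 and 277.5 in NCI-H1299. ZNF703, a transcriptional repressor, stood at 253 in HEK-293T, 6.45 in HuH-7 and 0.318 in NCI-H1299. TM4SF1, a tetraspanin-like surface protein, stood at 419 in NCI-H1299, 105 in HuH-7 and a listed 0 in HEK-293T. SPINK1, a trypsin inhibitor, and FABP1, the liver fatty acid binding protein, stood at 466 and 447 in HuH-7 and at a listed 0 in both other libraries. The FPKM sum of 1792 ribosomal protein pseudogenes was 0.459 times that of the ribosomal protein genes in HEK-293T, 0.256 times in HuH-7 and 0.193 times in NCI-H1299.

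Of the tests that follow, those of short RNA, of mitochondrial DNA and of scaling were chosen after the result was seen, and so were the corrections for GC content and gene length, whose bounds were set before their results. The centring by GC content was changed once after its first result was seen, so that a chromosome could not centre itself. The choice of these 3 patterns was also made after results were seen. A test of greater depth of the NCI-H1299 library was run and left out. Ribosomal protein genes were compared by length and with their pseudogenes, and those values are given with no explanation weighed.

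Most structured noncoding RNAs were higher in the NCI-H1299 library than in both others. Histone mRNAs, which RNA polymerase II makes, were also high there, with relative medians of 6.48 over HEK-293T and 5.72 over HuH-7. Higher output of RNA polymerase III would not account for the histone mRNAs. It could have been present as well, so these values cannot decide whether it raised the structured RNAs. For loss of short RNA from the other libraries, other mRNA genes of at most 1000 bases were examined. Their relative medians were -0.80 (929 genes, over HEK-293T) and -0.24 (888 genes, over HuH-7). These values argue against a loss that reaches RNA of up to 1000 bases. They cannot decide on a loss limited to much shorter RNA, since the set was not restricted to such genes. Loss of RNA without a poly(A) tail from the HEK-293T and HuH-7 libraries may account for the pattern, because histone mRNAs lack that tail and the smaller of their 2 relative medians was 5.715, past the bound of 2 set before. Such a loss would have been incomplete in HEK-293T, where RN7SL1 and RN7SL2 stood at 524 and 559, against 5.88 and 1.41 in HuH-7 and 12050 and 9815 in NCI-H1299. The mitochondrial ribosomal RNAs RNR1 and RNR2 were instead lowest in the NCI-H1299 library, which was not weighed for or against such a loss. They stood at 32.5 and 23.1 in NCI-H1299, 326 and 847 in HEK-293T and 2037 and 23336 in HuH-7. Of 15 mitochondrially encoded genes, 12 were at least 2-fold higher in NCI-H1299 than in HEK-293T, and 1 than in HuH-7. The labels give 1 protocol for all libraries. A difference in how ribosomal RNA was removed, or between the cell lines, was not tested and stays open.

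Mitochondrial messages were high in the HuH-7 library. Mitochondrial DNA is argued against, since the log2 ratio to HEK-293T of ND6, the coding gene on the other strand, less the median of the other 12 coding genes was -5.50. Scaling by 1 factor per library moves all genes alike, and would leave the 13 coding genes level with all genes. Their median lay 6.72 above that of all genes (quartiles 5.44 and 7.62). The mitochondrial share of the library had already been seen, and no such factor alters it. This outcome was thus known beforehand and is not a separate test. More mitochondria together with their nuclear-encoded parts is argued against as well, since the nuclear respiratory chain list had a relative median of -0.74. The pattern may therefore be a difference in mitochondrial RNA itself or in its recovery, and between these no test was run.

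Genes of chromosome 19 were low in the HuH-7 library against HEK-293T, with a relative median of -1.22. Gene length is argued against, since after centring by length the median was still -0.95. Without genes whose symbols start with ZNF it was -1.26, but 288 of the 298 genes remained. Zinc finger genes under other symbols were not tested, and those left out were too few to set the median. After centring by transcript GC content it was -0.358, above the bound of -0.4 set before, though its interval (-0.453 to -0.202) reaches past that bound and excludes 0. A GC content bias between the libraries may thus account for most of the pattern and not for all of it. Chromosome copy number was not tested and stays open.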
